A study of Homo sapiens with 4 samples.

How the data were processed

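MelJuSo melanoma cells were cultured in dishes, treated for 2 h and washed, and total RNA was extracted with Trizol and cleaned on columns with DNase, per the labels' protocols. Biotin-labelled RNA was hybridised to 1-colour Illumina expression beadchips, 1 array per group and 4 arrays in all. The groups were taken from the treatment given in the sample labels.

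The authors deposited non-normalized intensity values, 1 mean bead signal per probe and array, in which no background subtraction was visible (lowest value 30.1, highest 36890.5). A detection p-value accompanies each signal, per the file headers; how it was computed is not given in the sources used here. A second deposited table holds the authors' normalized values, which appeared to be on a log2 scale at the bright end. The submitters' processing notes name lumi, with no version, and the transform, background step and normalization method are not given in the sources used here. Within each array these values had the same rank order as the signal (Spearman's rho of 1), and they were identical to the series' value table (largest difference 0). Their medians over all probes were 2.28 for untreated, 2.18 for aclarubicin, 2.30 for doxorubicin and 2.12 for the combination; their exact scale and centring stay unknown, so they served only as an alternative.

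The non-normalized signals were background-corrected with limma 3.58.1 in R 4.3.3 by normexp, with the negative-control level inferred from the detection p-values and an offset of 16, quantile-normalized over the 4 arrays and taken to log2. Quantile normalization gives every array the same distribution, so a shift of most genes on an array is removed. A probe was detected at a detection p-value under 0.01. Of 48803 probes, 27578 carried 1 gene symbol in the platform annotation, 13 carried several and 21212 were unnamed here. Entrez identifiers of 27541 named probes matched a current gene table (assembly GRCh38.p14, used for names only), and 0 symbols changed. Probes detected on at least 1 array numbered 15695, of which 13140 had 1 symbol. A gene was represented by its probe of highest mean level, giving 10077 genes. The number of arrays limits the precision.

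Every array pair was compared by the log2 difference, with 2-fold as the threshold and no test, since each group has 1 array. Where a gene was detected on only 1 of the 2 arrays, the fold is a lower bound, taken against the higher of the dim array's lowest detected level and the probe's own value. The 35 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Lists of small nucleolar RNA, very long and intronless genes were added to these after seeing the data. A list's median was set against 10000 random lists of equal size matched on mean level in 20 bins, and called apart below the 2.5th percentile or as far up at the other end, which about 1 list in 20 reaches by chance; lists with fewer than 3 measured genes got no percentile. Lists share genes, so their calls are not independent. Members of one list can also vary together, unlike random genes, so more than 1 list in 20 can stand apart by chance. Named genes are the 8 highest and 8 lowest of each comparison with untreated cells among genes detected on both arrays whose other detected probes changed the same way, up to 3 bounds per direction, the 6 highest and 6 lowest between treatments by the same limit of detection on both arrays, the 2 highest and 2 lowest members of each list, and TOP2A, TOP2B, TOP1, H2AX, CDKN1A and MDM2. Probe disagreement is the SD of the difference between 2 probes of a gene divided by the square root of 2.

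Alternatives were no background correction, median scaling, cyclic loess, the authors' normalized values, the mean over probes, genes detected on all 4 arrays, no detection filter, thresholds of 1.5-fold and 3-fold, an offset of 50 and, chosen after seeing the data, no scaling between arrays. Shared-control simulations drew 100 sets of unchanged arrays. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The calling of genes and lists was tested on simulated data over 10077 genes for aclarubicin minus untreated, built on the normalized untreated levels. With 200 genes changed, 98.0% of those changed by 1.5 log2 units and 100% of those changed by 2.5 were called in the right direction. Of the unchanged genes, 0 were called. The simulated noise was smaller than the probe disagreement, so that 0, the 98.0% and the 100% followed largely from the setting. They do not give the rates for the real arrays. Background correction and normalization were not part of this test. In the simulated combination minus untreated, where genes varied independently, 5.8% of 1000 unchanged lists were called apart.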

Results

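Gene expression was measured on Illumina expression beadchips in MelJuSo, a human skin melanoma cell line, after short exposure to drugs that act on topoisomerase II. The series holds 4 arrays, 1 for each of 4 groups: untreated cells, cells given aclarubicin at 10 µM, cells given doxorubicin at 9 µM, and cells given etoposide at 10 µM together with aclarubicin at 10 µM. In the treated groups exposure lasted 2 h, the drug was washed out, and RNA was taken 1 day after removal. The labels give no such times for the untreated cells, so their time in culture may differ. Whether the paired drugs were added at once or in sequence is not given in the sources used here. Doxorubicin and etoposide trap topoisomerase II on cleaved DNA, whereas aclarubicin hinders the enzyme from acting on DNA. With 1 array per group there is no replicate spread, so no p-value is given and every difference below compares arrays, not conditions. The error available is technical: for 1229 genes with a pair of probes detected on all arrays, the probes' log2 differences from untreated disagreed with an SD of 0.41 for aclarubicin, 0.32 for doxorubicin and 0.46 for the combination.

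The arrays did not detect the same number of probes. Of 48803 probes, 13521 were detected in untreated cells, 9864 after aclarubicin, 14773 after doxorubicin and 9128 after the combination. The 75th percentile of the non-normalized signal was 88.0 in untreated cells, 66.7 after aclarubicin, 97.7 after doxorubicin and 63.2 after the combination. Its 99th percentile was 5473 in untreated cells, 6896 after aclarubicin, 5098 after doxorubicin and 6116 after the combination. Values were compared after quantile normalization, over 10077 genes detected on at least 1 array. Without scaling between arrays, an alternative chosen after seeing the data, the median gene differed from untreated by -0.66 log2 after aclarubicin, 0.06 after doxorubicin and -0.92 after the combination. Under median scaling these medians were 0.64, -0.06 and 0.69.

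The first comparison asked what aclarubicin changed. Among genes detected on both arrays, the highest against untreated cells were ID2, an inhibitor of helix-loop-helix transcription factors, at 114-fold, RN7SK, the small nuclear RNA that holds the elongation factor P-TEFb inactive, at 68.5-fold, and FOSB, an AP-1 subunit, at 63.4-fold. GADD45B was 26.6-fold, FOS 15.3-fold, ID1 12.4-fold, VCX3B 11.8-fold and VCX 10.5-fold higher. RIMBP3, INSM2 and SNORD46 were detected after aclarubicin and not in untreated cells, at least 20.7-fold, 18.3-fold and 16.3-fold higher. The lowest genes detected on both arrays were DKK1, a secreted Wnt antagonist, 66.6-fold lower, the cyclin gene CCNA2, 22.4-fold lower, MALSU1, 20.8-fold lower, and SPRED1, a brake on RAS signalling, 18.9-fold lower. DCUN1D5, SNAR-A1, PGRMC2 and SERTAD2 were 16.9-fold, 15.8-fold, 15.2-fold and 15.1-fold lower. UCN2, GOLPH3 and PRRC2C were no longer detected after aclarubicin, at least 17.0-fold, 13.4-fold and 12.2-fold lower. Without scaling, the folds of the leading genes detected on both arrays were 0.60 to 0.92 times those given for the higher genes and 0.99 to 1.75 times for the lower ones.

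Of the gene lists, those of dividing cells lay low after aclarubicin. Among 44 genes of G2/M and mitosis, 27 were at least 2-fold lower and 0 higher, with a median log2 difference of -1.42, below all 10000 random lists matched on level. KIF11, the mitotic kinesin, differed by -3.79. Among 36 genes of G1/S and replication, 18 were lower and 0 higher (median -0.88, percentile 0.01), PCNA by -3.03 and RFC4 by -2.92. Of 41 DNA repair and damage signalling genes, 15 were lower and 2 higher (median -0.66, percentile 0.12): MSH6 differed by -3.61, whereas XRCC2 differed by 2.07. The median of this list was 0.002 under median scaling. Ribosome biogenesis and Pol I genes had 18 of 39 lower and 1 higher (median -0.89, percentile 0.01), WDR75 by -3.33. MAPK and NRAS output genes had 10 of 17 lower and 1 higher (median -1.51, percentile 0.035), and EGR1, at 3.03, was the exception. Heat shock genes had 6 of 19 lower and 1 higher (median -0.63, percentile 0.18), HSPA8 by -2.68, and HSPA6 was at least 4.58-fold higher. Their median turned to 0.54 under median scaling.

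Replication-dependent histone genes went the other way. Of 23 measured, 20 were at least 2-fold higher after aclarubicin and 1 lower (median 1.74, above all matched lists). H4C1 and H2BC21 were at least 6.63-fold and 6.13-fold higher, and H4C3, at -2.55, was the lower one. MHC class I and II genes had 11 of 24 higher and 2 lower (median 0.95, percentile 99.99), HLA-F by 1.88 and HLA-G by 1.72. Lysosome and autophagy genes had 11 of 31 higher and 3 lower (median 0.60, percentile 98.6), TPP1 by 1.96. Cholesterol genes had 8 of 17 higher and 3 lower (median 0.78, percentile 97.9, apart under 5 of 9 alternatives, and -0.11 without scaling), with MVD at 1.69 and SQLE at -3.17. The p53 target genes did not stand apart (4 of 32 higher, 6 lower, median 0.06, percentile 66.1, but 0.68 under median scaling and -0.62 without scaling), with PMAIP1 at 1.64, and PPM1D at -2.12. Among the lists above, medians that moved by over 1.5 times were, under median scaling, -0.69 for G2/M, -0.26 for G1/S, -0.32 for ribosome biogenesis, -0.97 for MAPK, 1.88 for MHC, 1.75 for lysosome and 1.19 for cholesterol genes. Without scaling they were -1.56 for G1/S, -1.30 for DNA repair, -1.62 for ribosome biogenesis, -2.27 for MAPK, 0.97 for histone and 0.58 for MHC genes.

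In all, 1572 genes were at least 2-fold higher after aclarubicin and 2251 lower, so 41.1% of the changed genes were higher. That split follows the scaling: 73.8% were higher under median scaling (3980 against 1414), 6.32% without scaling (278 against 4120), and 59.0% among genes detected on all 4 arrays (1351 against 940). Of 34 lists given a percentile, 6 lay above and 9 below matched lists. Lists of unrelated genes would give 1.7 by chance, and lists whose members vary together can give more.

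**Figure D1:**
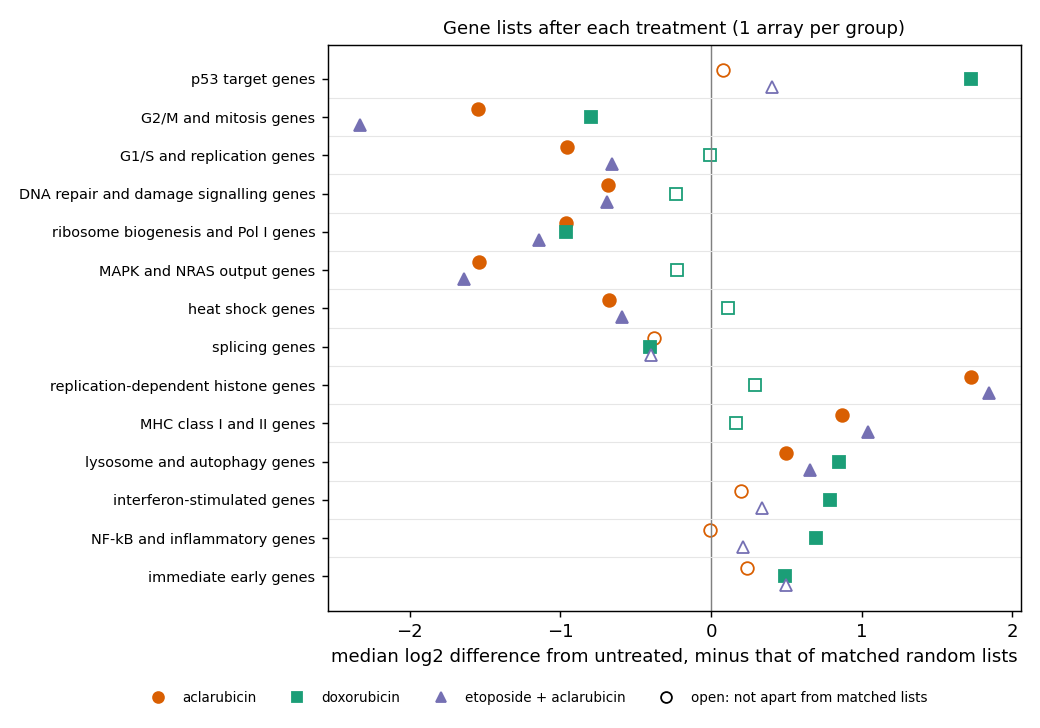
Median log2 difference from untreated of 14 gene lists (x axis, log2 units) minus the median of random lists matched on level, for aclarubicin (circles), doxorubicin (squares) and etoposide plus aclarubicin (triangles), 1 array each; open symbols did not stand apart from matched lists. The p53 target genes stand high after doxorubicin (median 1.73), and the replication-dependent histone genes after aclarubicin (1.74) and the combination (1.82).

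Doxorubicin, the second comparison, gave another set of leading genes, RN7SK excepted. TP53I3, a quinone oxidoreductase induced by p53, was 70.6-fold higher than in untreated cells, RN7SK 67.3-fold, ACTA2, smooth muscle actin, 67.1-fold, the imprinted non-coding RNA H19 39.3-fold, and SUGCT 38.6-fold. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was 32.6-fold, TMEM158 20.8-fold and TLCD1 18.9-fold higher. C1QTNF1, the galanin receptor gene GALR2 and the aldo-keto reductase gene AKR1B10 were not detected in untreated cells and were at least 207-fold, 135-fold and 84.6-fold higher. The lowest detected on both arrays were HNRNPA1P10 and CMSS1, both 11.3-fold lower, and the transcription factor gene SOX9, 10.9-fold lower. PFAS, a purine synthesis enzyme, SLC39A11, MYC, the ribosomal protein gene RPS7 and FJX1 were 9.58-fold, 9.57-fold, 9.38-fold, 9.14-fold and 9.05-fold lower. TENM3, PLCB1 and SLC35F1 were no longer detected, at least 7.25-fold, 6.74-fold and 6.72-fold lower. Without scaling, the folds of the leading genes detected on both arrays were 0.48 to 0.84 times those given for the higher genes and 0.68 to 0.78 times for the lower ones. TP53I3 then differed by 5.09 on the log2 scale, less than RN7SK at 5.34 and ACTA2 at 5.21.

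The p53 target genes were the list that stood highest after doxorubicin among lists given a percentile, with 24 of 32 members at least 2-fold higher and 0 lower (median 1.73, above all matched lists). MDM2, the p53 ligase, was detected only on this array, at least 2.77-fold higher than in untreated cells. Interferon-stimulated genes had 10 of 23 higher and 0 lower (median 0.83, percentile 99.97), TAP1, a peptide transporter of the MHC class I pathway, by 3.45 and ISG20 by 3.27. NF-kB and inflammatory genes had 5 of 16 higher and 1 lower (median 0.72, percentile 99.7), PTGS2 by 2.94. Lysosome and autophagy genes had 12 of 31 higher and 2 lower (median 0.81, above all matched lists), CTSF by 2.57. Immediate early genes had 10 of 29 higher and 4 lower (median 0.43, percentile 99.4), EGR1 by 4.04 and ATF3 by 3.45 against MYC at -3.23. After aclarubicin they had 12 higher and 6 lower (percentile 76.2), and after the combination 12 higher and 6 lower (percentile 92.1), apart in neither. Matrix, TGF-beta and senescence-associated genes had 9 of 22 higher and 5 lower (median 0.56, percentile 99.7), ID2 by 3.18 and THBS1 by -2.56. Oxidative stress and iron genes had 7 of 24 higher and 2 lower (median 0.37, percentile 98.6), with HMOX1 at least 9.67-fold higher and the transferrin receptor gene TFRC at -2.88; 4 of 9 alternatives kept that list apart. Under median scaling the medians were 0.13 for this list and 0.54 for lysosome genes, and in the authors' normalized values 1.10 for NF-kB genes.

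Lists that lay low after doxorubicin included ribosome biogenesis and Pol I genes, 20 of 39 lower and 0 higher (median -1.02, below all matched lists), BOP1 by -2.56 and DKC1 by -1.92. G2/M and mitosis genes had 14 of 44 lower and 2 higher (median -0.85, below all matched lists), CDC20 by -2.36, while G1/S and replication genes did not stand apart (median -0.06, or -0.14 under median scaling, percentile 48.6, PCNA at 1.36). Splicing genes had 12 of 46 lower and 1 higher (median -0.45, percentile 0.14), HNRNPA2B1 by -2.43. Unfolded protein response genes had 4 of 27 lower and 1 higher (median -0.40, percentile 1.47, apart under 4 of 9 alternatives, median -0.26 under cyclic loess), HSPA5 by -2.10. Replication-dependent histone genes had 5 of 23 higher and 0 lower (median 0.22, percentile 92.8, but 0.52 in the authors' normalized values and 0.44 without scaling), and H2AC18 was the highest at 3.65. In all, 1341 genes were at least 2-fold higher and 1040 lower. Of the 34 lists, 7 lay above and 5 below matched lists.

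The third comparison set etoposide plus aclarubicin against untreated cells, and its leading genes overlapped those of aclarubicin alone. ID2 was 146-fold higher, FOSB 94.1-fold, RN7SK 93.0-fold, GADD45B 38.6-fold, ID1 21.3-fold, FOS 16.6-fold, ACTA2 16.4-fold and SNORD43 15.4-fold. RN7SK was thus a leading gene of every comparison with the shared untreated array, where a low reading could raise it in each. RIMBP3, INSM2 and SNORD46 were at least 33.0-fold, 32.4-fold and 22.4-fold higher. DKK1 was 63.0-fold lower, MALSU1 22.8-fold, PTBP3 21.0-fold, STK24 19.5-fold, SNAR-A1 19.2-fold, NOL11 18.6-fold and DCUN1D5 18.2-fold lower, and PGRMC2 differed by -4.32. CCNA2, KIF11 and SPRED1 were not detected, at least 35.3-fold, 25.1-fold and 17.4-fold lower than in untreated cells. Folds of the leading genes detected on both arrays were, without scaling, 0.52 to 0.87 times those given for the higher genes and 1.26 to 1.98 times for the lower ones.

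Of the lists, G2/M and mitosis genes had 33 of 44 lower and 0 higher after the combination (median -2.25, below all matched lists), and G1/S and replication genes 14 of 36 lower and 0 higher (median -0.61, percentile 0.43, but 0.20 under median scaling). Ribosome biogenesis genes had 22 of 39 lower and 1 higher (median -1.12, percentile 0.01), WDR75 and DKC1 by -3.58 each, and MAPK and NRAS output genes 10 of 17 lower and 2 higher (median -1.64, percentile 0.06). DNA repair genes had 14 of 41 lower and 2 higher (median -0.69, percentile 0.43), with TOPBP1 at least 8.99-fold lower, and heat shock genes 5 of 19 lower and 1 higher (median -0.57, percentile 1.1, apart under 7 of 9 alternatives, but 1.04 under median scaling). Replication-dependent histone genes had 21 of 23 higher and 1 lower (median 1.82), and MHC genes 12 of 24 higher and 2 lower (median 1.10), both above all matched lists. Lysosome genes had 13 of 31 higher and 3 lower (median 0.71, percentile 99.3). The p53 target genes had 6 of 32 higher and 2 lower (median 0.35, percentile 94.6, but 1.15 under median scaling and -0.46 without scaling), with PMAIP1 at 2.44. Other medians that moved by over 1.5 times were, under median scaling, -1.41 for G2/M, -0.45 for ribosome biogenesis, -0.97 for MAPK, -0.18 for DNA repair, 2.13 for MHC and 1.81 for lysosome genes. Without scaling they were -1.40 for G1/S, -2.06 for ribosome biogenesis, -2.58 for MAPK, -1.78 for DNA repair, 0.86 for histone, 0.52 for MHC and 0.20 for lysosome genes. In all, 1867 genes were higher and 2547 lower (42.3% higher). The share higher was 73.6% under median scaling (4192 against 1507), 5.69% without scaling (291 against 4825) and 59.5% among genes detected on all 4 arrays (1545 against 1053). Of the 34 lists, 7 lay above and 7 below matched lists.

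The topoisomerase genes themselves differed between treatments. TOP2A, the target isoform of dividing cells, differed from untreated by -1.72 after aclarubicin, -0.03 after doxorubicin and -2.34 after the combination, and TOP2B by -0.73, -1.15 and -1.22. TOP1 differed by 0.50 after aclarubicin and 0.26 after doxorubicin, and was not detected after the combination. H2AX, the histone variant marked at DNA breaks, differed by -1.08, -2.37 and -1.31, and CDKN1A by 0.18, 5.03 and 0.92. Without scaling, CDKN1A differed by -0.70, 4.08 and -0.15, and TOP1 by -0.43 after aclarubicin and 0.53 after doxorubicin. TOP2B then differed by -1.44 after aclarubicin and -2.34 after the combination, TOP2A by -0.17 after doxorubicin and H2AX by -2.16 after the combination. The list of topoisomerases with anthracycline transport and metabolism genes did not stand apart in any of the 3 comparisons with untreated cells (percentiles 29.3, 89.2 and 20.6).

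**Figure D2:**
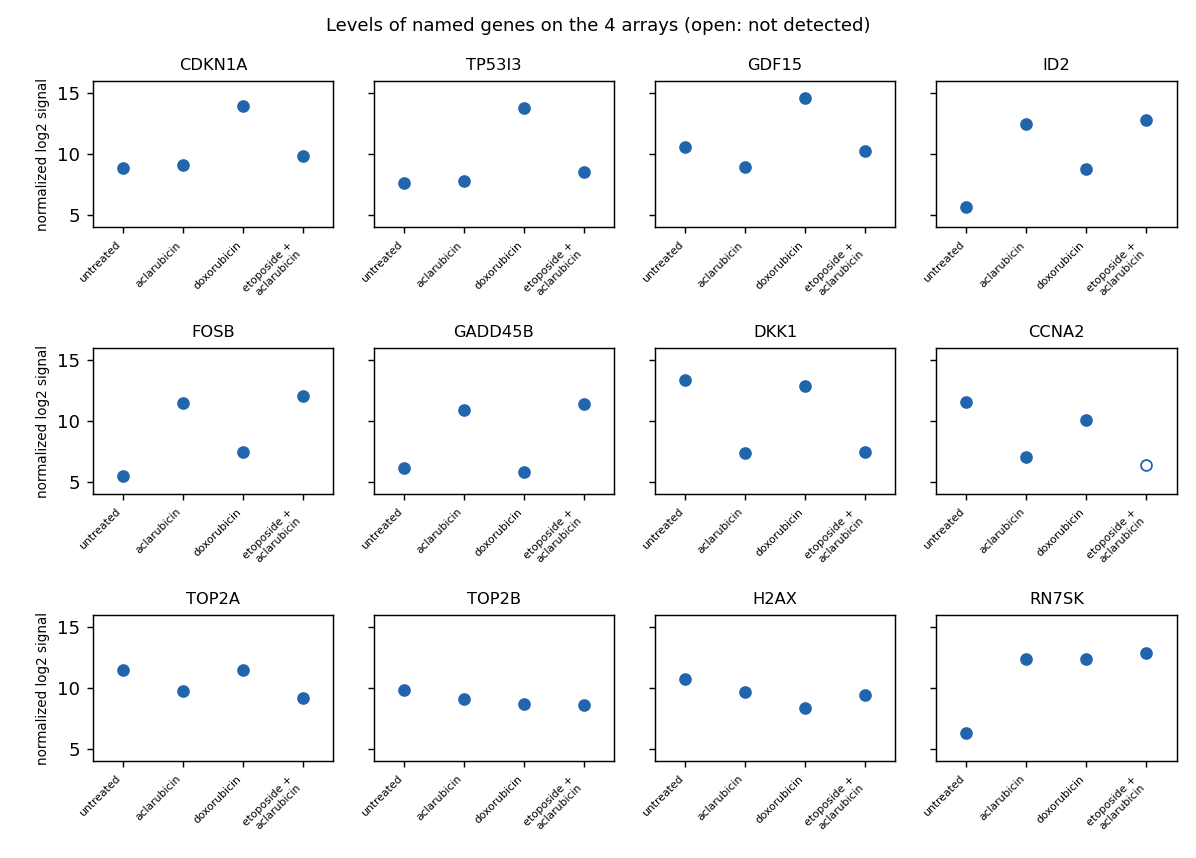
Quantile-normalized log2 signal (y axis) of 12 named genes on the 4 arrays, 1 point per array; open points were not detected. CDKN1A stood at 13.9 after doxorubicin and between 8.90 and 9.82 on the other arrays, and RN7SK stood at 6.31 in untreated cells and between 12.4 and 12.8 after treatment.

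Aclarubicin and doxorubicin are both anthracyclines: doxorubicin carries 1 amino sugar, daunosamine, and aclarubicin a chain of sugars whose amino group is dimethylated. Their doses here were 10 and 9 µM, close but not equal, at the same 2 h exposure. Set directly against each other among genes detected on both arrays, doxorubicin exceeded aclarubicin most for TP53I3 (64.1-fold), GDF15, a secreted stress cytokine (51.1-fold), DKK1 (45.9-fold), AVPI1 (34.6-fold), SERTAD2 (33.3-fold) and SUGCT (30.5-fold). It lay below aclarubicin most for GADD45B (33.0-fold), the ribosomal protein gene RPL36A (19.4-fold), FOSB (16.7-fold), RSU1 (16.4-fold), SRI (16.1-fold) and POLR3G (15.7-fold). Without scaling these folds were 1.02 to 1.39 times as large for the higher genes and 0.55 to 0.65 times for the lower ones. CDKN1A differed by 4.85 and TOP2A by 1.69 on the log2 scale, doxorubicin minus aclarubicin, where the probe disagreement was 0.50. Of p53 target genes, 24 of 32 were higher after doxorubicin and 0 lower (median 1.99, above all matched lists), G1/S and replication genes 19 of 36 against 5 lower (median 1.01, percentile 99.99), MAPK and NRAS output genes 10 of 17 against 2 lower (median 1.39, percentile 99.8), and heat shock genes 10 of 19 against 2 lower (median 1.06, percentile 99.98). Replication-dependent histone genes had 14 of 23 lower and 2 higher (median -1.68, below all matched lists, apart under 8 of 9 alternatives), and MHC genes 9 of 24 lower and 2 higher (median -0.58, percentile 1.81, apart under 5 of 9 alternatives). Under median scaling these medians were 1.22 for p53 target, 0.10 for G1/S, 0.64 for MAPK, 0.18 for heat shock and -1.73 for MHC genes. Without scaling they were 1.53 for G1/S, 1.60 for heat shock, -0.93 for histone and -0.30 for MHC genes. The histone median was -2.88 in the authors' normalized values and the MHC median -0.38 under cyclic loess. Among genes detected on all 4 arrays, the histone median differed from that of matched lists by -0.25, against -1.73 over the 23 measured. Ribosome biogenesis genes showed no shared direction, with 7 of 39 higher and 7 lower (median 0.02, percentile 53.3, but -0.81 under median scaling, 0.11 under cyclic loess and 0.62 without scaling); without replicates, no interval can be put on that difference. In all, 2714 genes were higher and 1887 lower after doxorubicin (59.0% higher), and 1426 of the higher ones were not detected after aclarubicin. The share was 31.3% under median scaling (1619 against 3555), 88.0% without scaling (4974 against 677) and 41.2% among genes detected on all 4 arrays (1107 against 1577). The median gene differed by 0.22, by -0.45 under median scaling and by 0.98 without scaling.

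**Figure D3:**
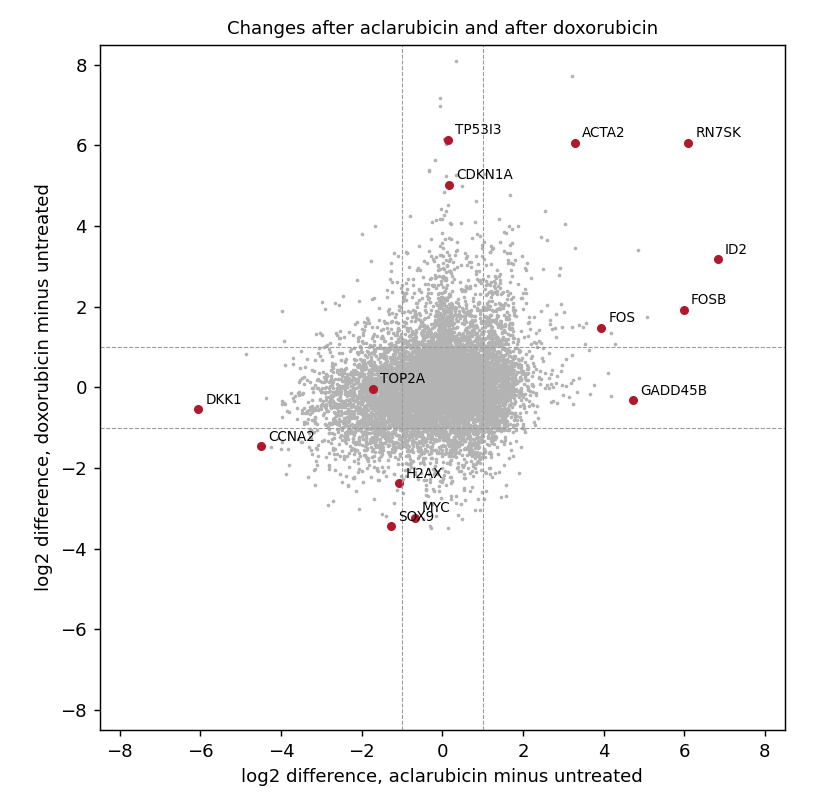
Log2 difference from untreated of 10077 genes after aclarubicin (x axis) and doxorubicin (y axis), 1 point per gene, with named genes in red and dashed lines at 2-fold. TP53I3 and CDKN1A lie high for doxorubicin and near 0 for aclarubicin, GADD45B and FOSB lie high for aclarubicin, and RN7SK lies high for both.

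The combination array differed from the aclarubicin array by 2-fold at fewer genes than any other of the 6 pairs of arrays. Against aclarubicin alone, 81 genes were at least 2-fold higher and 232 lower, and the levels correlated across genes at r = 0.98, against 0.80 to 0.90 for the other 5 pairs (genes are not replicates). Among genes detected on both arrays, HAND1 was 3.41-fold, RFTN2 2.74-fold, IL12A 2.69-fold, FOXQ1 2.55-fold, ZNF280A 2.54-fold and GDF15 2.52-fold higher. The lamin gene LMNB1 was 3.21-fold, SLC2A1 and NOC3L 3.06-fold, the splicing factor gene SRSF3 3.03-fold, DYM 2.84-fold and MBNL2 2.77-fold lower. Without scaling these folds were 0.83 to 0.94 times as large for the higher genes and 1.26 to 1.37 times for the lower ones. Of the 34 lists, 10 lay above matched lists and 1 below. The 1 below was G2/M and mitosis genes, with 12 of 44 lower and 0 higher (median -0.60, below all matched lists). G1/S and replication genes went the other way, with 1 of 36 higher and 0 lower (median 0.13, percentile 99.69). That list stood apart under 8 of 9 alternatives, and its median was -0.10 without scaling. Among p53 target genes, 2 of 32 were higher and 0 lower (median 0.37), and 0 of 29 immediate early genes passed 2-fold (median 0.51); both medians lay above all matched lists. Without scaling the medians were -0.90 for G2/M, 0.08 for p53 target and 0.28 for immediate early genes. CDKN1A differed by 0.75, where the probe disagreement was 0.17. H2AX differed by -0.23, but its other detected probe went the opposite way. The share of higher genes was 25.9% here, 36.3% in the authors' normalized values (494 against 868) and 2.96% without scaling (13 against 426). The median gene differed by -0.01, by 0.11 under median scaling and by -0.20 without scaling.

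Against doxorubicin, among genes detected on both arrays, the combination array was highest for GADD45B (47.9-fold), FOSB (24.7-fold), RPL36A (24.3-fold), SNORD43 (20.7-fold), INSM2 (17.8-fold) and SOX2 (17.2-fold). It was lowest for DKK1 (43.4-fold), TP53I3 (37.7-fold), PFKFB4 (34.6-fold), VCF1 (33.1-fold), SERTAD2 (31.9-fold) and AVPI1 (30.3-fold). Without scaling these folds were 0.45 to 0.60 times as large for the higher genes and 1.26 to 1.67 times for the lower ones. G2/M and mitosis genes had 28 of 44 lower (median -1.48) and p53 target genes 20 of 32 lower (median -1.76), with 0 higher in either list and both medians below all matched lists, and replication-dependent histone genes 16 of 23 higher and 1 lower (median 1.88, above all matched lists, apart under 8 of 9 alternatives). Under median scaling the medians were -0.97 for G2/M and -0.73 for p53 target genes, and without scaling -2.71 for G2/M and 0.89 for histone genes, the histone median being 3.13 in the authors' normalized values. Among genes detected on all 4 arrays, the histone median differed from that of matched lists by 0.48, against 1.98 over the 23 measured. H2AX differed by 1.06 where the probe disagreement was 0.53, and by -0.18 without scaling. The median gene differed by -0.27, by 0.53 under median scaling and by -1.20 without scaling. In all, 1940 genes were higher and 2855 lower (40.5% higher), and 1690 of the lower ones were not detected on the combination array. The share higher was 70.1% under median scaling (3673 against 1563), 8.01% without scaling (492 against 5647) and 58.7% among genes detected on all 4 arrays (1616 against 1136).

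Changes from untreated were compared between treatments over the 10077 genes. Aclarubicin and the combination shared 1430 higher and 2024 lower genes, and 0 went opposite ways (r = 0.95). Aclarubicin and doxorubicin shared 320 higher and 364 lower genes, and 217 went opposite ways (r = 0.21). For doxorubicin and the combination the shared genes were 410 higher and 448 lower, with 214 opposite (r = 0.27). Independent lists of these sizes would share 291 higher and 569 lower genes in the first case, 209 and 232 in the second, and 248 and 263 in the third. No such number was computed for genes that went opposite ways, so 217 and 214 cannot be read as many or few. These counts follow the scaling: for aclarubicin and the combination they were 3697 higher and 1210 lower under median scaling, and 212 and 3996 without scaling. Shared higher genes were 897 and 90 under these scalings for aclarubicin and doxorubicin, and 1001 and 109 for doxorubicin and the combination; expected numbers were not recomputed. All 3 comparisons use the same untreated array, and simulated unchanged arrays sharing it gave r = 0.50. Equal noise on arrays that share 1 control gives that r at any noise level, so it is no yardstick for the observed values. With noise set from the closest pair of arrays, 9.5 higher and 8.64 lower genes were shared. The covariances were 1.48, 0.237 and 0.362, beside a simulated 0.068, or 0.029 with noise from probe disagreement. With 1 untreated array, the share of each overlap that comes from that array was not separated.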

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

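Probes with no gene name here took no part in the comparisons above, and 2555 of them were detected on at least 1 array. Against the untreated array, 515 were at least 2-fold higher after aclarubicin and 341 lower, 253 higher and 242 lower after doxorubicin, and 599 higher and 408 lower after the combination. What drew attention is a signal above the untreated array in data outside the gene comparisons. Genes with a higher signal were found too, but the split was not the same. Of the 10077 genes, 1572 were higher and 2251 lower after aclarubicin. After doxorubicin 1341 were higher and 1040 lower, and after the combination 1867 and 2547. After aclarubicin and the combination, higher outnumbered lower among the unnamed probes, and lower outnumbered higher among genes. The cause was not tested. For genes the split followed the scaling, and the probes are counted here under 1 scaling only. No group has enough arrays to look for an array far from its group.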

How the results depend on the processing

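The alternative without scaling, and the small nucleolar RNA, very long and intronless lists, were added after seeing the data. No paired analysis was possible because each group has 1 array. Counts of changed genes depended most on scaling and on the threshold; 79 of 132 counts stayed within 1.5 times the reported one, and those that did not follow. Under median scaling, the counts were 3980 higher and 1414 lower for aclarubicin minus untreated, 4192 higher and 1507 lower for combination minus untreated, 1619 higher and 3555 lower for doxorubicin minus aclarubicin, 132 lower for combination minus aclarubicin and 3673 higher and 1563 lower for combination minus doxorubicin. At a threshold of 1.5-fold, the counts were 2716 higher for aclarubicin minus untreated, 2421 higher and 2225 lower for doxorubicin minus untreated, 2943 higher for combination minus untreated and 597 higher and 894 lower for combination minus aclarubicin. At a threshold of 3-fold, the counts were 451 higher and 1173 lower for aclarubicin minus untreated, 652 higher and 309 lower for doxorubicin minus untreated, 748 higher and 1483 lower for combination minus untreated, 1535 higher and 892 lower for doxorubicin minus aclarubicin, 7 higher and 28 lower for combination minus aclarubicin and 1005 higher and 1676 lower for combination minus doxorubicin. Without scaling, the counts were 278 higher and 4120 lower for aclarubicin minus untreated, 291 higher and 4825 lower for combination minus untreated, 4974 higher and 677 lower for doxorubicin minus aclarubicin, 13 higher and 426 lower for combination minus aclarubicin and 492 higher and 5647 lower for combination minus doxorubicin. Among genes detected on all 4 arrays, the counts were 940 lower for aclarubicin minus untreated, 732 higher for doxorubicin minus untreated, 1053 lower for combination minus untreated, 1107 higher for doxorubicin minus aclarubicin, 17 higher and 57 lower for combination minus aclarubicin and 1136 lower for combination minus doxorubicin. With an offset of 50, the counts were 692 lower for doxorubicin minus untreated and 18 higher and 69 lower for combination minus aclarubicin. Without background correction, the counts were 21 higher and 83 lower for combination minus aclarubicin. Under cyclic loess, the counts were 50 higher and 122 lower for combination minus aclarubicin. In the authors' normalized values, the counts were 494 higher and 868 lower for combination minus aclarubicin. Another threshold or a smaller set of genes changes a count by construction; for the rest the cause was not tested. Of 66 counts of genes shared between changes from untreated, 32 stayed within 1.5 times the reported one, and the other 34 were these. Under median scaling, they numbered 3697 higher and 1210 lower for aclarubicin and the combination, 897 higher for aclarubicin and doxorubicin and 1001 higher for doxorubicin and the combination. At a threshold of 1.5-fold, they numbered 2460 higher for aclarubicin and the combination, 758 higher and 961 lower for aclarubicin and doxorubicin and 898 higher and 1117 lower for doxorubicin and the combination. At a threshold of 3-fold, they numbered 425 higher and 1081 lower for aclarubicin and the combination, 79 higher and 68 lower for aclarubicin and doxorubicin and 125 higher and 96 lower for doxorubicin and the combination. Without scaling, they numbered 212 higher and 3996 lower for aclarubicin and the combination, 90 higher for aclarubicin and doxorubicin and 109 higher for doxorubicin and the combination. Among genes detected on all 4 arrays, they numbered 818 lower for aclarubicin and the combination, 160 lower for aclarubicin and doxorubicin and 207 lower for doxorubicin and the combination. Without background correction, they numbered 203 higher and 242 lower for aclarubicin and doxorubicin and 266 higher and 295 lower for doxorubicin and the combination. In the authors' normalized values, they numbered 584 higher and 579 lower for aclarubicin and doxorubicin and 715 higher and 679 lower for doxorubicin and the combination. With an offset of 50, they numbered 189 higher and 232 lower for aclarubicin and doxorubicin and 249 higher and 286 lower for doxorubicin and the combination.

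For lists that stood apart, added lists included, the excess of the median over matched lists kept its sign under every alternative, and it was called apart except as follows. Among genes detected on all 4 arrays, it was -0.37 (DNA repair) for aclarubicin minus untreated, -0.38 (unfolded protein), 0.12 (oxidative stress) for doxorubicin minus untreated, -0.49 (DNA repair), 0.35 (intronless), 0.38 (intronless with left-out put back) for combination minus untreated, 0.49 (G2/M), -0.25 (histone), 0.13 (oxidative stress), -0.55 (MHC) for doxorubicin minus aclarubicin, 0.0587 (apoptosis), 0.20 (MAPK) for combination minus aclarubicin and 0.48 (histone), -0.91 (MAPK), 0.39 (intronless), 0.42 (intronless with left-out put back) for combination minus doxorubicin. With the mean over probes, it was -0.33 (unfolded protein), -0.51 (apoptosis) for aclarubicin minus untreated, -0.36 (unfolded protein), 0.32 (oxidative stress) for doxorubicin minus untreated, 0.24 (oxidative phosphorylation) for combination minus untreated, 0.54 (apoptosis), 0.46 (oxidative stress), -0.32 (oxidative phosphorylation) for doxorubicin minus aclarubicin, 0.0918 (G1/S), 0.11 (apoptosis) for combination minus aclarubicin and 0.53 (intronless) for combination minus doxorubicin. Under median scaling and without scaling alike, it was -0.52 (histone chaperones), -0.51 (unfolded protein), -0.28 (apoptosis), 0.75 (cholesterol) for aclarubicin minus untreated, -0.59 (histone chaperones), -0.38 (heat shock), 0.93 (fibroblast), 0.46 (intronless) for combination minus untreated, -0.19 (oxidative phosphorylation) for doxorubicin minus aclarubicin, 0.13 (histone), 0.13 (interferon), 0.13 (MHC), 0.17 (Wnt), 0.20 (MAPK) for combination minus aclarubicin and 1.14 (endothelial), 0.39 (intronless) for combination minus doxorubicin. Under cyclic loess, it was -0.41 (unfolded protein), -0.45 (apoptosis) for aclarubicin minus untreated, -0.24 (unfolded protein), 0.35 (oxidative stress), 0.28 (intronless), 0.26 (intronless with left-out put back) for doxorubicin minus untreated, 0.21 (oxidative phosphorylation), 1.22 (fibroblast) for combination minus untreated, 0.48 (oxidative stress), -0.24 (oxidative phosphorylation), -0.50 (MHC), -0.66 (Wnt) for doxorubicin minus aclarubicin, 0.14 (histone) for combination minus aclarubicin and 0.0792 (ribosomal protein), 1.28 (endothelial) for combination minus doxorubicin. Without background correction, it was -0.33 (unfolded protein), -0.37 (apoptosis) for aclarubicin minus untreated and 0.12 (MHC), 0.17 (MAPK) for combination minus aclarubicin. In the authors' normalized values, it was -0.31 (unfolded protein), 0.74 (cholesterol) for aclarubicin minus untreated, -0.30 (unfolded protein), 0.39 (oxidative stress), 0.30 (intronless with left-out put back) for doxorubicin minus untreated, 0.19 (oxidative phosphorylation), 2.11 (fibroblast) for combination minus untreated, 0.45 (oxidative stress), -0.24 (oxidative phosphorylation), -0.48 (MHC), -0.76 (Wnt) for doxorubicin minus aclarubicin and -0.45 (heat shock), 0.0898 (ribosomal protein), 3.13 (fibroblast), 2.64 (endothelial) for combination minus doxorubicin. Without a detection filter, it was -0.25 (unfolded protein), -0.26 (apoptosis), 0.25 (cholesterol), 0.0840 (leukocyte) for aclarubicin minus untreated, -0.13 (unfolded protein), 0.15 (oxidative stress), -0.13 (metallothioneins), 0.0907 (matrix and TGF-beta), 0.0464 (intronless), 0.0451 (intronless with left-out put back) for doxorubicin minus untreated, 0.25 (oxidative phosphorylation), 0.0816 (fibroblast) for combination minus untreated, -0.30 (oxidative phosphorylation), -0.31 (MHC), -0.23 (Wnt) for doxorubicin minus aclarubicin, 0.0649 (interferon), 0.0734 (apoptosis), 0.0418 (Wnt), 0.14 (MAPK) for combination minus aclarubicin and 0.13 (Wnt), 0.0571 (fibroblast), 0.0409 (endothelial), 0.0763 (very long), 0.10 (very long with left-out put back) for combination minus doxorubicin. With an offset of 50, it was -0.31 (unfolded protein), -0.31 (apoptosis), 0.46 (metallothioneins) for aclarubicin minus untreated and 0.0733 (apoptosis), 0.11 (MHC), 0.16 (MAPK) for combination minus aclarubicin. Median scaling and no scaling give one excess by construction, as they differ by 1 constant per array. A list with fewer than 3 genes under an alternative got no value there. The cause of the other losses was not tested. The p53 target genes after doxorubicin kept their call under all 9, as did G2/M, ribosome biogenesis, histone, MHC, MAPK and lysosome genes wherever they stood apart against untreated cells. Over all lists and pairs, added lists included, 1877 list values kept their call, 123 lost it and 82 gained it.

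Of log2 differences of named genes, 3064 moved by less than the probe disagreement, 1330 by more, and 12 past 2-fold turned sign. Without scaling, signs turned for H2AX (combination minus doxorubicin), at -0.18, H2AJ (combination minus untreated), at -0.0483, EHMT2 (combination minus untreated), at -0.0334, CAT (combination minus untreated), at -0.0355 and EPHA2 (combination minus untreated), at -0.0200. With the mean over probes, signs turned for TDP1 (aclarubicin minus untreated), at -0.27, TDP1 (combination minus untreated), at -0.26, LAMP2 (doxorubicin minus untreated), at 0.16 and RPL34 (doxorubicin minus untreated), at -0.51. In the authors' normalized values, signs turned for MITF (aclarubicin minus untreated), at 0.62 and MITF (combination minus untreated), at 0.47. Under median scaling, signs turned for THBS1 (aclarubicin minus untreated), at 0.51. The cause was not tested. The root mean square difference in the authors' normalized values was 0.78 for combination minus aclarubicin and 2.18 for combination minus doxorubicin, against 0.42 and 1.45; 52 other such values and 36 correlations of changes stayed within 1.5 times. Signal over background limits the dim genes: of 2251 genes lower after aclarubicin, 1143 were detected on both arrays.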

Other observations

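Tests of the explanations below were chosen after the results they bear on were seen, except the test of very long genes after aclarubicin. The list used in that test was itself written after the leading genes were seen. Small nucleolar RNA genes, which guide modification of ribosomal RNA, were made a list only after some were seen among the leading genes, so their counts describe the arrays and test nothing. Of 38 measured, 18 were at least 2-fold higher and 2 lower after aclarubicin (median log2 difference 0.93, or -0.0022 without scaling), 23 higher and 2 lower after the combination (median 1.46, or 0.13 without scaling), and 1 higher and 6 lower after doxorubicin (median -0.71, or -1.26 in the authors' normalized values). Of metallothioneins, which bind zinc, 2 of 5 were higher after aclarubicin (median 0.84, percentile 98.1) and 4 after the combination (median 2.04, percentile 99.99), while 3 were lower after doxorubicin (median -1.11, percentile 0.27), MT2A by -2.70. The calls after aclarubicin and doxorubicin each held under 7 of 8 alternatives. Their median was 1.88 after aclarubicin under median scaling, 1.57 in the authors' normalized values, and 0.82 after the combination without scaling.

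Among markers of other cell types, 4 of 17 leukocyte genes were measured, at percentiles 99.8, 90.7 and 99.8 after aclarubicin, doxorubicin and the combination, the first apart under 7 of 8 alternatives. CD14 was at least 12.2-fold higher after aclarubicin. The 3 measured fibroblast genes had medians of 1.06, 0.10 and 1.38 (percentiles 97.1, 47.2 and 97.8, the last apart under 3 of 8 alternatives), or 0.11, 0.35 and 0.19 without scaling. The 4 endothelial genes had medians of 0.29, -0.06 and 0.71, which under other scalings ran from -0.0073 to 1.29, -0.17 to 0.13 and 0.0645 to 1.67. Of the keratinocyte genes 2 were measured, and SFN, also a p53 target, was at least 32.2-fold higher after doxorubicin. Melanocyte lineage genes did not stand apart (percentiles 74.3, 79.8 and 66.0), though SOX10 differed by -3.36 after aclarubicin and TYRP1 by -2.80 after doxorubicin. Housekeeping genes had medians of -0.06, -0.08 and -0.01, which under other scalings ran from -0.27 to 1.54, -0.34 to -0.0919 and -0.29 to 1.67.

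Other lists, in the order aclarubicin, doxorubicin and combination against untreated, gave these percentiles. Histone variants lay at 76.2, 34.8 and 79.5, histone chaperones and chromatin modifiers at 0.88, 7.84 and 1 (after aclarubicin and the combination each apart under 7 of 9 alternatives), RNA polymerase II genes at 15.3, 40.9 and 8.83, and proteasome genes at 32.5, 10.0 and 15.9. Glycolysis and hypoxia genes lay at 70.9, 18.5 and 88.7, Wnt, Notch and Hippo targets at 49.8, 30.8 and 47.5, cytosolic ribosomal proteins at 22.2, 3.3 and 57.4, and oxidative phosphorylation genes at 94.2, 33.0 and 98.9 (the last apart under 5 of 9). Apoptosis regulators lay at 1.74, 96.5 and 40.4, with FADD at -3.20 after aclarubicin, and unfolded protein response genes at 2.29, 1.47 and 9.05. After aclarubicin these calls held under only 2 of 9 alternatives for apoptosis and 1 of 9 for unfolded protein genes. Their medians of -0.68 and -0.52 both turned to 0.33 under median scaling, as those of histone chaperones did, from -0.57 to 0.27 after aclarubicin and from -0.66 to 0.20 after the combination. Intronless genes, added after seeing the data, lay at 86.7, 98.98 and 99.2, apart under 7 of 9 alternatives after doxorubicin and 6 of 9 after the combination. Their medians of 0.29 after aclarubicin and 0.65 after the combination turned to -0.74 and -0.59 without scaling.

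Fewer probes were detected on both arrays of aclarubicin-treated cells than in untreated cells. Arrays dimmer throughout would lower the bright end too, but the 99th percentile of signal was at least 1.12 times the untreated one on both. The 95th percentile was lower, at 746 after aclarubicin and 598 after the combination against 1147 in untreated cells. These values argue only against dimming of the whole range. Loss of transcripts from very long genes is not borne out after aclarubicin, where a list of 37 measured ones lay at percentile 39.1 of matched lists, and at 76.9 with 6 genes put back that had been left out for being seen among the leading genes. After the combination it stays open, as these percentiles were 15.12 and 12.01, low but short of the limit. A few transcripts taking most of the signal cannot be told apart from a loss of the other signal: the share of the 500 brightest probes was at least 13.1 percentage points higher on both arrays, but it rises in either case. The treatment itself and RNA quality stay open, as each group has 1 array.

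The combination array lay close to the aclarubicin array. One RNA hybridised on both would leave only noise between them, but 2 probes of one gene moved together (r = 0.73 after removing the trend with level), although a difference in labelling would also be shared by probes. Etoposide may add part of the response seen after doxorubicin. Combination minus aclarubicin correlated across genes with doxorubicin minus untreated, which shares no array with it. After removing that trend r was 0.30 (0.25 to 0.36 over the alternatives without it). Of genes higher after doxorubicin, 68.4% were positive in combination minus aclarubicin, against 25.8% of those lower and 48.8% of the other genes. Their medians in it were 0.13, -0.22 and -0.0079 log2, where the probe disagreement was 0.17. Given aclarubicin minus untreated, which shares an array with each of the correlated differences, the partial r was 0.26. Noise on those shared arrays alone makes this partial r positive, so it does not weigh one explanation against the other. A larger aclarubicin response is also consistent with the data, with r = 0.26 against aclarubicin minus untreated, although noise on the shared array lowers that r. Etoposide alone was not analysed here, so both stay open.

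Very long genes were noticed among those lowest after doxorubicin, such as TENM3. A list of 37 others, known for their length, had 17 at least 2-fold lower and 2 higher, and its median lay -0.95 below that of matched lists, below all of them. High levels on the shared untreated array do not explain this, as the list also lay -0.91 below matched lists in doxorubicin minus aclarubicin, at percentile 0.03, although its own median there was -0.48, and 0.21 without scaling. As a hypothesis, doxorubicin may lower transcripts of very long genes more than others; gene lengths themselves were not used here, and the list rests on textbook knowledge.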
